A study of Homo sapiens with 4 samples.

How the data were processed

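Total RNA of DU145 cells was extracted with TRIzol, amplified to biotin-labelled cRNA with an Ambion MessageAmp kit and hybridised to Illumina bead arrays, per the labels' protocols. The 4 arrays fall into mock (2 arrays) and VprBP-depleted (2 arrays), as the labels name them. The scanner software, its settings and a genome build are not given in the sources used here, and no coordinates are printed.

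The authors deposited a table with a bead signal and a detection p-value per probe and array. The signal is an intensity on a linear scale, per the file headers and its values, neither background-subtracted nor scaled between arrays. The deposited detection p-value moves in steps that imply 770 negative controls per array. The authors also deposited processed intensity values. On 3498 probes with a mean raw signal over 2000, 100% of these equalled the raw signal less an amount that differed between probes by whole numbers (tolerance 0.01). They are linear, with medians of 90.4 and 98.6 on the mock arrays and 86.2 and 90.4 on the depleted arrays, so they were not scaled between arrays. How the subtracted background was obtained is not given in the sources used here, and 64 probes have no processed value.

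The raw signals were processed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with negative control statistics inferred from the detection p-values (offset 16), followed by quantile normalization and log2 (function neqc). Background left in the signal and a larger offset both make the fold changes of dim probes smaller, so these depend on both. A probe was kept when its detection p was below 0.05 on at least 2 of 4 arrays, which left 22866 of 47135 probes. The platform annotation gave 1 gene symbol for 30021 probes and several for 8, and 17106 probes are unnamed here. Symbols were updated through Entrez identifiers, and 39 probes without a current match kept the older symbol. Each gene was represented by its kept probe with the highest mean log2 signal. This gave 12559 genes. Of these, 3437 had several detected probes, and among 662 such genes that passed, another probe passed in the same direction for 227 and in the opposite direction for 9.

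VprBP-depleted and mock arrays were compared with lmFit and eBayes (two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Standard errors are the moderated ones. Where no array of a group detected a gene, the fold is a bound: the mean of the other group over the mean of, per array, the higher of the probe's own value and the lowest value among detected probes. The bound holds only for this background correction, offset and scaling, and the fold can be smaller in the alternatives. Among the genes that passed, 181 had a group below background.

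The design, the rule for named genes, 36 gene lists and most alternatives were fixed before the data were examined. The genes named are DCAF1, the 12 with the largest rise and the 12 with the largest fall among genes that passed and whose groups did not overlap, and up to 4 members per list that passed with the largest change (where none passed, up to 2 by smallest p, as values). Other genes in the closing section were chosen after their values were seen. Of 1205 list genes, 1111 were matched to a named probe, and the other 94 are not analysed here. The lists with at least 5 tested genes (31) were tested with camera at a preset correlation of 0.01, adjusted over lists.

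The procedure was tested on simulated data with 2 arrays per group, 12683 genes and 200 changed genes. It recovered 0% of changes of 0.5 on the log2 scale, 24% of changes of 1, 93.5% of changes of 1.5 and 89.1% of changes of 2. Of 99 calls 3 were false. A list shifted by 0.4 was found, and 0 of 30 other lists passed. That shift was added after normalization and the simulated noise was independent between genes, so lists of correlated genes were not tested. Changes of 1 or smaller were mostly missed in the simulation. The real data gave 2559 calls, with a median absolute log2 fold change of 0.73 and a smallest of 0.42. With so many more calls, the simulated rates do not carry over to the real data.

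The alternatives were no background correction, an offset of 50, scaling on the median of all probes, cyclic loess, the deposited processed values, no detection filter or a stricter one (p below 0.01 on all 4 arrays), the mean of a gene's probes, all probes, the replicate number as a block, a trended robust eBayes, array weights, each array left out in turn, an adjusted p threshold of 0.1, treat against a 1.2-fold change, and camera with an estimated correlation or fry. Scaling on the median of probes detected on all 4 arrays, and no scaling between arrays, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.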

Results

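Gene expression was measured on Illumina bead arrays in DU145 cells, an established human cancer line, after knockdown of VprBP and in mock cells. The sample titles mark the depleted cells VprBPsh and the mock cells NCsh, without spelling these out. The labels describe the cells as bladder cancer, whereas DU145 is generally catalogued as a prostate carcinoma line. VprBP, encoded by DCAF1, is a substrate receptor of the CUL4-DDB1 ubiquitin ligase that also acts on histone H2A in chromatin. Each group held 2 arrays, numbered replicate 1 and replicate 2, and the labels do not say whether the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Of 47135 probes, 22289 and 23186 were detected on mock replicates 1 and 2, and 21568 and 21807 on VprBP-depleted replicates 1 and 2, at a detection p below 0.05. The median raw signal was 140 and 155 on the mock arrays and 129 and 138 on the depleted arrays. After normalization, 12559 genes were tested. Arrays of the same group correlated at 0.992 (mock) and 0.995 (depleted) across these genes, and arrays of different groups at 0.974 to 0.978. Genes are not independent replicates, and the number of arrays limits the precision of every value below.

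The first comparison asked whether the targeted transcript was lower in the depleted cells. DCAF1 (probe ILMN_2181089, the only probe named for it) fell 2.64-fold, to 37.9% of the mock level (95% interval of the fold, 1.99 to 3.50). Its normalized log2 signal was 7.18 ± 0.031 (SD, n = 2) in mock cells and 5.78 ± 0.29 (SD, n = 2) in depleted cells, a log2 fold change of -1.40 ± 0.16 (SE) with a limma adjusted p of 0.0070. Raw signals were 254 and 305 on the mock arrays against 141 and 168 on the depleted arrays. Both depleted signals were close to background, with detection p of 0.026 and 0.010, so the size of the fall depended on the background step: the log2 fold change was -0.63 with no background correction, still past the threshold.

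VprBP depletion was followed by changes in both directions. Of the 12559 genes tested, 1108 were higher and 1451 lower in depleted cells at a limma adjusted p below 0.05, which is 20.4% of the genes. Among them, 184 rose and 369 fell at least 2-fold, against 58 and 114 with no background correction, 101 and 179 with an offset of 50, and 59 and 1079 with no scaling between arrays. IL11, a cytokine of the interleukin-6 family, showed the largest rise (11.3-fold, log2 fold change 3.49 ± 0.12 SE, adjusted p = 0.0021), and C1QL4 the largest fall (8.18-fold, log2 fold change -3.03 ± 0.19 SE, adjusted p = 0.0025). The depleted C1QL4 signals (5.53 and 5.51) lay close to the lowest detected signals on those arrays (5.26 and 5.23). Its log2 fold change ran from -3.35 to -1.65 over the alternatives, so its size depends on the processing.

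Among the 12 largest rises, several were non-coding RNAs. RMRP, the RNA of the RNase MRP complex, rose 8.66-fold, and the small Cajal body RNAs SCARNA18, SCARNA11 and SCARNA23, a class that guides the modification of spliceosomal RNAs, rose 6.37-fold, 5.62-fold and 4.52-fold. A probe for 18S ribosomal RNA (RNA18SN5) rose 5.24-fold, and cannot tell the near-identical copies of that gene apart. The antisense transcript SLC67A1-AS rose 4.39-fold. The remaining 6 were protein-coding: IL11, the hormone receptor AMHR2 (5.05-fold), the matricellular protein CCN3 (4.52-fold), the aryl hydrocarbon-inducible enzyme CYP1A1 (4.35-fold), the BH3-only protein BMF (4.31-fold) and the interleukin-6 receptor IL6R (3.88-fold).

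The 12 largest falls included the secreted phosphoprotein SPP1, also called osteopontin (6.40-fold), and CYP24A1 and CYP26A1, which degrade active vitamin D and retinoic acid (6.37-fold and 4.82-fold). The class II histocompatibility gene HLA-DPA1 fell 5.13-fold. HLA-DOB fell at least 4.68-fold in these values, a bound because neither depleted array detected it above background. Its log2 fold change ran from -2.70 to -1.05 over the alternatives. SNORD13, a small nucleolar RNA, fell 5.15-fold, against the direction of the small Cajal body RNAs. GALNT16, SRPX, the endoplasmic reticulum protein ERLIN2, the chemokine CCL20 and DDIT4L fell 5.75-fold, 5.09-fold, 4.94-fold, 4.77-fold and 4.60-fold. The fall of ERLIN2 rested on 1 of its 3 detected probes, since the other probes had log2 fold changes of -0.27 (adjusted p = 0.33) and -0.12 (0.69). The limma adjusted p of these 24 genes was between 0.0021 and 0.0072, and the 2 depleted values lay on one side of the 2 mock values for each.

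**Figure D1:**
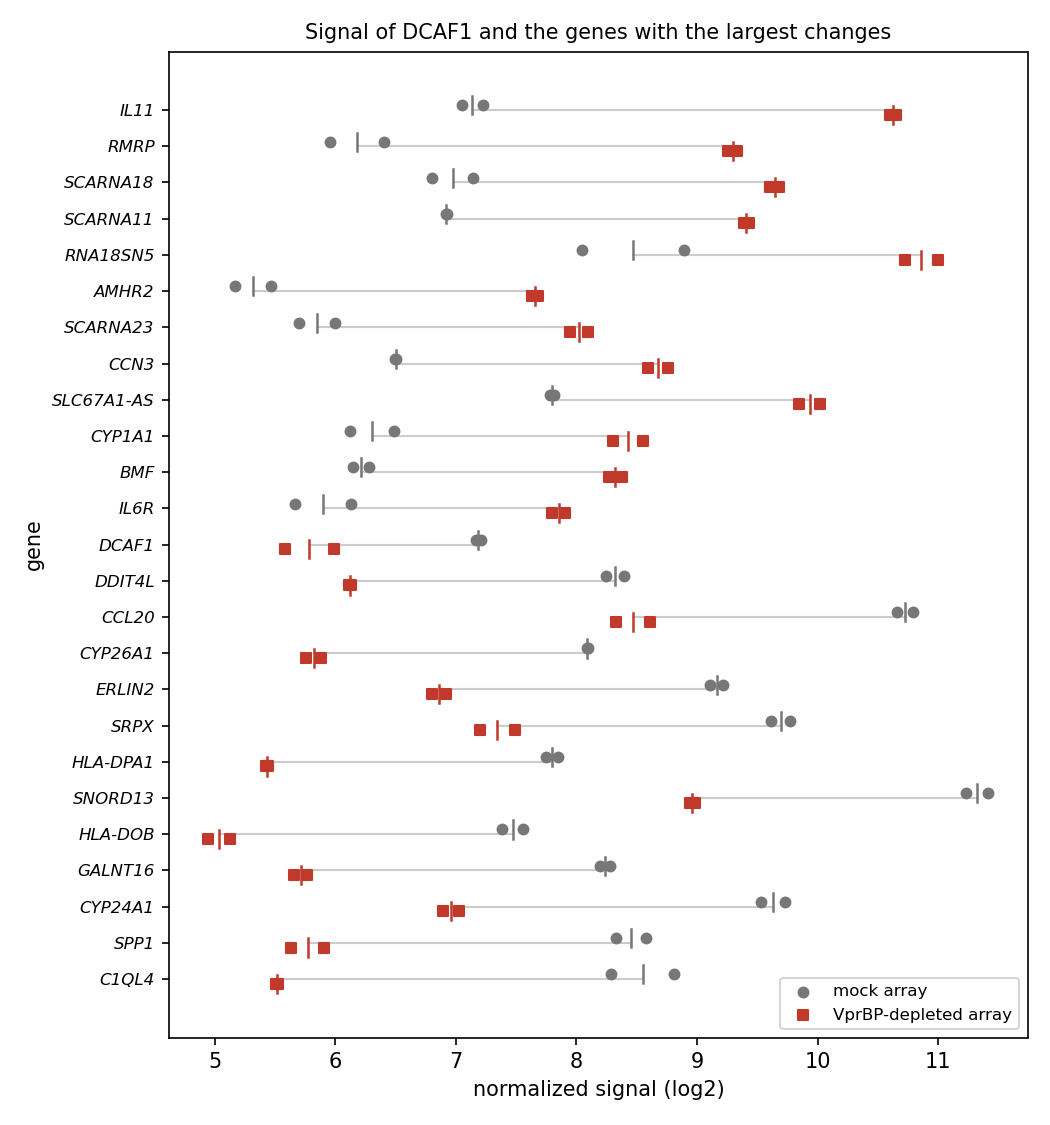
Normalized log2 signal (x axis) of DCAF1, the 12 genes with the largest rise and the 12 with the largest fall (y axis). Grey circles are the 2 mock arrays, red squares the 2 VprBP-depleted arrays and short vertical lines the group means. IL11 stands at 7.14 in mock and 10.63 in depleted cells, and DCAF1 at 7.18 and 5.78.

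The counts moved with single arrays and the balance of directions with the scaling. Without mock replicate 1, VprBP-depleted replicate 1 or VprBP-depleted replicate 2, the 2559 calls became 1064, 830 or 843. Higher genes made up 43.3% of the calls after quantile normalization, 18.6% after scaling on the median of all probes and 5.37% in the deposited processed values, which are not scaled between arrays and put the median of all genes at -0.27. With the same background correction and no scaling they made up 5.64%. DCAF1 and the 24 genes above passed in every setting in which they were tested, but the sizes moved. The log2 fold change ran from 1.07 to 2.49 for AMHR2 and from -2.67 to -1.12 for HLA-DPA1, against 2.76 to 3.58 for IL11. Of the 120 named genes other than DCAF1 that passed, 47 and 31 no longer did without mock replicate 1 or 2, and 56 and 60 without VprBP-depleted replicate 1 or 2. None changed sign. Of 32 named genes with another detected probe, 11 had another that passed in the same direction and 21 did not. The 21 include CENPA, AURKA, RAD17, PRMT5, PSMB8, DSC2, ITGB5, SREBF1, ATP5F1D and HSPA2, whose other probes kept the direction without passing. For the rest, the other probes are described where the gene is named.

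The list of the unfolded protein response and of amino acid supply under the transcription factor ATF4 shifted lower. Of 39 measured members, 16 fell, 2 rose and 21 did not pass (23 lower and 2 higher when adjusted over the list alone). PDIA4 and HSPA5, folding factors of the endoplasmic reticulum, fell 3.47-fold and 2.33-fold, and ASNS, asparagine synthetase, fell 2.46-fold. PPP1R15A, a phosphatase subunit that reverses the stress-induced block of translation, rose 2.42-fold. The median log2 fold change was -0.43, and the set test (camera, preset correlation) gave an adjusted p of 3.4e-05. It gave adjusted p = 0.45 with an estimated correlation, although that estimate (-0.011) lay below the preset 0.01. Of the 31 lists tested, 6 passed with the preset correlation and 0 with an estimated correlation, where 1 had an unadjusted p below 0.05. The version with an estimated correlation had 2 residual degrees of freedom and so little power, and a list that fails it is left undecided. With no scaling between arrays the unfolded protein response and ATF4 list alone passed (adjusted p = 0.00018). The directional test fry, which does not compare a list with other genes, called this list, G2 and mitosis, immediate early genes and, unlike camera, DNA replication and S phase.

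Some genes of the cell division machinery fell. In the list for G2 and mitosis, 6 of 49 members fell (12.2%, against 11.6% of all genes), 43 did not pass and none rose (4 lower when adjusted over the list alone), with a median log2 fold change of -0.20. ESPL1, the protease separase, fell 2.23-fold, the spindle motor KIF11 1.64-fold, the centromeric histone CENPA 1.5-fold and the kinase AURKA 1.48-fold. The camera adjusted p was 0.010 (adjusted p = 0.45 with an estimated correlation), and it was 0.054 without VprBP-depleted replicate 1 and 0.12 with no scaling between arrays. In the list for DNA replication and S phase, 9 of 51 members fell and none rose (7 lower when adjusted over the list alone). The phosphatase CDC25A (1.70-fold), POLE2 (1.62-fold), ORC1 (1.58-fold) and the licensing factor CDC6 (1.51-fold) led these falls. That list did not pass camera (adjusted p = 0.16, and adjusted p = 0.65 with an estimated correlation) but passed fry (adjusted p = 0.035). A second CDC25A probe had a log2 fold change of 0.28 (adjusted p = 0.25). Among G1 cyclins and their kinases, CDC25A and CDK6 (1.59-fold) fell and 13 of 15 members did not pass (list adjusted p = 0.83), and the same 2 members passed when adjusted over the list alone.

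More genes of glycolysis and the hypoxic response fell than rose, although most did not pass. Of 35 members, 10 fell, 1 rose and 24 did not pass, and the counts were equal when adjusted over the list alone. The glucose transporter SLC2A3 fell at least 3.54-fold, to below background on both depleted arrays. Its log2 fold change ran from -2.25 to -0.79 over the alternatives. The phosphofructokinase PFKL fell 2.49-fold, NDRG1 2.03-fold and INSIG2 1.89-fold. The camera adjusted p was 0.010 (adjusted p = 0.90 with an estimated correlation), and fry did not call the list (0.074). Alone among the called lists, its estimated correlation (0.11) lay above the preset 0.01, so the preset test may overstate the evidence for it. The call was lost without mock replicate 2 (adjusted p = 0.18), after scaling on the median of all probes (0.069) or on detected probes (0.071), and with no scaling (0.12).

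The lists of targets of the transcriptional coactivators YAP and TAZ, of immediate early genes and of ribosome biogenesis genes shifted higher relative to all genes. Of 28 YAP and TAZ targets, 8 rose and 1 fell (9 and 2 when adjusted over the list alone). Tissue factor F3, TGFB2 and THBS1 rose 2.60-fold, 2.24-fold and 2.01-fold, whereas IGFBP3, an insulin-like growth factor binding protein, fell 4.33-fold. The other F3 probe had a log2 fold change of 0.40 and did not pass (adjusted p = 0.11). Of 29 immediate early genes, 9 rose and 2 fell (11 and 3 when adjusted over the list alone). The phosphatase DUSP5 rose 2.33-fold and the transcription factor KLF10 2.24-fold, and EGR1 and SGK1 fell 3.23-fold and 2.62-fold. The other KLF10 probes had log2 fold changes of 1.02 and -0.015 and did not pass. Of 36 ribosome biogenesis genes, 6 rose and none fell (4 higher when adjusted over the list alone), led by UTP20 (1.79-fold), DDX10 (1.75-fold), UTP4 (1.53-fold) and POLR1A (1.52-fold). The other UTP20 probe had a log2 fold change of 0.21 (adjusted p = 0.43). The median log2 fold changes of the YAP and TAZ, immediate early and ribosome biogenesis lists were 0.26, 0.25 and 0.22. In the unscaled deposited values they were -0.083, -0.054 and -0.11, and with no scaling -0.098, -0.085 and -0.11, above the medians of all genes there (-0.27 and -0.34). The camera adjusted p was 0.010, 0.010 and 0.0087, and adjusted p = 0.45 with an estimated correlation for each. With no scaling between arrays the 3 lists did not pass (0.072, 0.10 and 0.056), nor did the immediate early list in the deposited values (0.066), and fry did not call the YAP and TAZ (0.074) and ribosome biogenesis (0.055) lists.

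**Figure D2:**
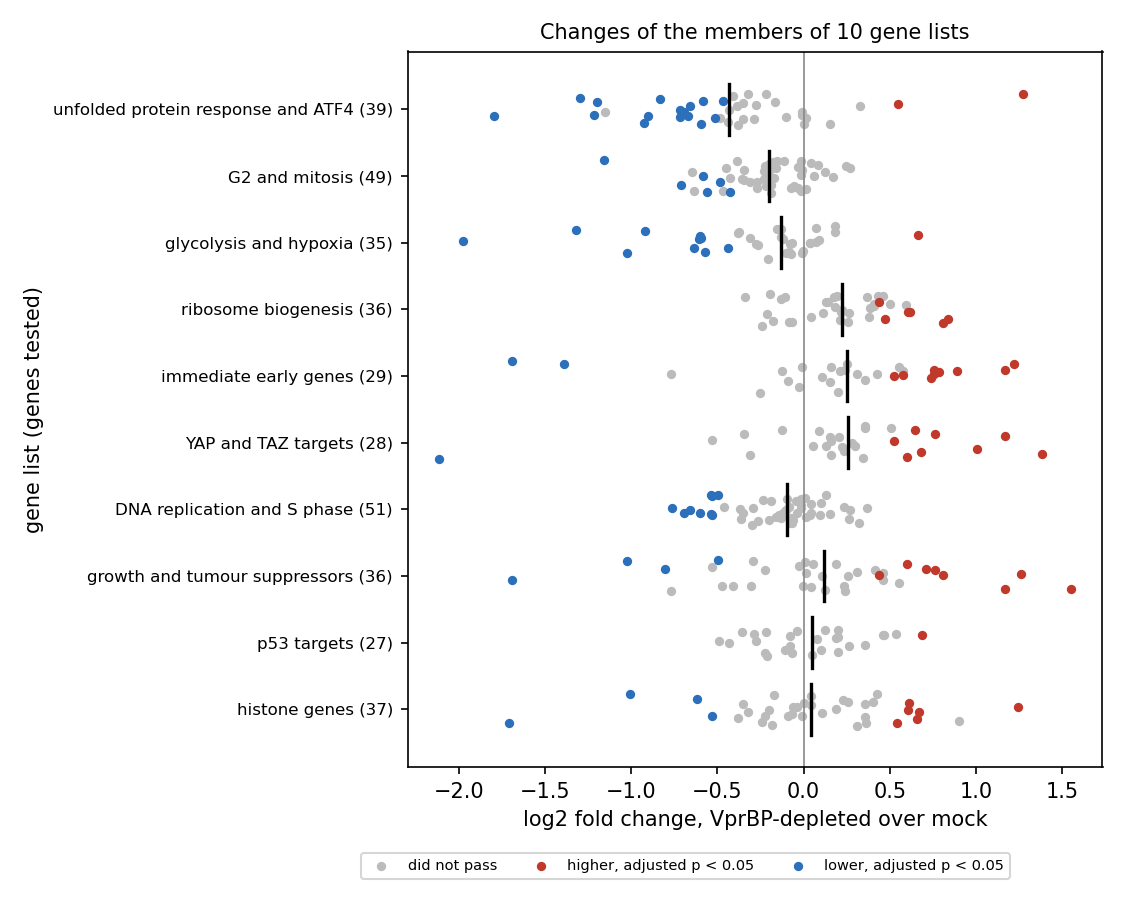
Log2 fold change of VprBP-depleted over mock cells (x axis) for the tested members of 10 gene lists (y axis, number of genes in brackets). Each point is 1 gene, red where it rose, blue where it fell and grey where it did not pass, and black lines are medians. The median of the unfolded protein response and ATF4 list lies at -0.43 and that of the YAP and TAZ list at 0.26, or -0.083 in the unscaled deposited values and -0.098 with no scaling.

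Regulators of growth and cell death changed gene by gene rather than as lists. Of 36 growth and tumour suppressors, 8 rose and 4 fell (10 and 8 when adjusted over the list alone; list adjusted p = 0.56). TXNIP, an inhibitor of glucose uptake, rose 2.93-fold and the antiproliferative gene TOB1 2.40-fold, next to KLF10 and the fall of EGR1. Of 34 pro-apoptotic genes, 2 rose and 2 fell (2 and 0 when adjusted over the list alone; list adjusted p = 0.83). BMF rose, and the death ligand TNFSF10 rose at least 3.0-fold from below background on both mock arrays. The log2 fold change of TNFSF10 ran from 0.67 to 2.05 over the alternatives. CASP6 and BCL2L11 fell 1.42-fold and 1.41-fold, but their other detected probes did not pass. Of 16 anti-apoptotic genes, CFLAR (2.19-fold), BCL2L2 (1.58-fold) and MCL1 (1.41-fold) fell and none rose, and the counts were equal when adjusted over the list alone (list adjusted p = 0.83). The other MCL1 probe had a log2 fold change of -0.13 and did not pass (limma adjusted p = 0.68). Among 27 p53 targets, TRIAP1 alone passed, with a 1.61-fold rise, and none passed when adjusted over the list alone (list adjusted p = 0.83). Of 29 partners of VprBP and other CUL4 ligase genes, the polarity gene LLGL1 alone passed, falling 1.44-fold, and none passed when adjusted over the list alone (list adjusted p = 0.89).

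Inflammatory and immune genes moved in both directions. Of 27 NF-kB targets and cytokines, 6 rose and 6 fell, also when adjusted over the list alone (list adjusted p = 0.83). These made up 44.4% of the list, against 20.4% of all genes, and camera looks only for a shift in one direction. IL11, TNFSF10 and TNFAIP2 (2.05-fold) rose, and CCL20 fell. Of 41 interferon response genes, 4 rose and 6 fell (4 and 8 when adjusted over the list alone; list adjusted p = 0.995). IFI44 fell 1.82-fold and IFITM1 at least 1.26-fold, and the immunoproteasome subunit PSMB9 and LGALS3BP rose 1.73-fold and 1.62-fold. The other PSMB9 probe had a log2 fold change of 0.20 and did not pass (limma adjusted p = 0.40). Of 19 antigen presentation genes, PSMB9, PSMB8 (1.37-fold) and PSMB10 (1.35-fold) rose, and HLA-DMA, which loads peptides onto class II molecules, fell 3.89-fold (3 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.83). PSMB10 lay at the threshold (limma adjusted p = 0.0497) and did not pass with cyclic loess or with the replicate number as a block.

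Genes of cell shape and adhesion likewise split. Of 28 mesenchymal and TGF-beta genes, 8 rose and 5 fell (8 and 8 when adjusted over the list alone; list adjusted p = 0.83), and the median of -0.020 and the mean of 0.070 had opposite signs. In all, 46.4% of this list changed, against 20.4% of all genes, a share that camera, which looks for a shift in one direction, does not judge. TGFB2 and THBS1 rose, and COL4A1 and ACTA2 fell 2.00-fold and 1.86-fold. Of 27 epithelial junction and keratin genes, CLDN7 (2.51-fold), ST14 (1.76-fold) and CDH3 (1.42-fold) fell and DSC2 rose 1.56-fold (0 higher and 3 lower when adjusted over the list alone; list adjusted p = 0.83). Among 26 integrins, laminins and matrix proteases, ITGA1 (detected on 1 of 2 depleted arrays) and MMP15 fell 2.36-fold and 1.59-fold, and MMP9 and ITGB5 rose 1.6-fold and 1.43-fold, with equal counts when adjusted over the list alone (list adjusted p = 0.90).

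Histone genes changed in both directions, and few histone-modifying enzymes changed. Of 37 histone genes, 6 rose and 4 fell (8 and 4 when adjusted over the list alone; list adjusted p = 0.83). The linker histone H1-10 fell 3.27-fold, H2BC8 fell 2.01-fold and H2AC19 rose 1.59-fold. For H3C13 the brightest probe rose 2.36-fold while another probe fell (log2 fold change -1.19, adjusted p = 0.028), so its direction is open, and the near-identical histone genes may share probes. Of 56 histone-modifying enzymes, 5 rose and 2 fell, and none passed when adjusted over the list alone (list adjusted p = 0.83). KDM6B (1.67-fold), PRMT5 (1.65-fold) and KDM2A (1.48-fold) rose and HDAC4 fell 1.46-fold. Among 40 DNA repair and checkpoint genes RAD17 alone passed, rising 1.45-fold, and none passed when adjusted over the list alone (list adjusted p = 0.83).

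The lists for cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, heat shock, lysosomes, antioxidants and the proteasome did not pass the set test. In cholesterol synthesis, TM7SF2 (2.59-fold), SREBF1 (1.75-fold), FASN (1.41-fold) and HMGCS1 (1.36-fold) fell and none of 25 rose (2 lower when adjusted over the list alone; list adjusted p = 0.83). HMGCS1 did not pass with the replicate number as a block. SREBF1 did not pass with the mean of a gene's probes, and its other probe had a log2 fold change of -0.47 (limma adjusted p = 0.35). Of 65 cytosolic ribosomal protein genes, 3 rose, among them RPL34 (1.81-fold) and RPL28 (1.65-fold), and 3 fell, among them RPL22 (1.69-fold) and RPL13A (1.38-fold), with 2 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.83). Of 52 oxidative phosphorylation genes, ATP5MC3 and ATP5F1D each fell 1.74-fold and NDUFS6 rose at least 1.25-fold (0 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.83). NDUFS6 did not pass with no background correction, an offset of 50, the deposited processed values or no scaling. Of 26 heat shock genes, HSPB8 fell at least 3.48-fold, CCT5 1.71-fold and HSPA2 1.58-fold, and DNAJA1 rose 1.46-fold, with equal counts when adjusted over the list alone (list adjusted p = 0.83, median 0.080 and mean -0.058). The log2 fold change of HSPB8, below background on both depleted arrays, ran from -2.37 to -0.84 over the alternatives. Of 39 lysosome and autophagy genes, 5 rose and 3 fell, also when adjusted over the list alone (list adjusted p = 0.87, median -0.035 and mean 0.024). The lysosomal regulator TFEB rose at least 1.48-fold and SQSTM1 1.53-fold, and CTSH and GAA fell 1.83-fold and 1.75-fold. Among 25 antioxidant genes, HMOX1, SOD2 and NQO1 rose 1.82-fold, 1.70-fold and 1.6-fold, also when adjusted over the list alone (list adjusted p = 0.83). The other NQO1 probe had a log2 fold change of 0.37 and did not pass (limma adjusted p = 0.53). None of 30 proteasome genes passed in limma, and 0 had an unadjusted p below 0.05 (list adjusted p = 0.83).

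Markers in the cell type lists were largely not detected, apart from the neuroendocrine list. Of the markers with a named probe, 4 of 14 prostate luminal, 4 of 12 urothelial, 4 of 13 fibroblast, 5 of 16 leukocyte, 1 of 12 endothelial and 5 of 10 neuroendocrine genes were detected. FKBP5 and STEAP2 of the prostate luminal list fell 1.76-fold and 1.64-fold. The urothelial plaque gene UPK1A fell 3.49-fold, while PPARG and FOXA1 rose 1.79-fold and 1.47-fold. ACTA2 of the fibroblast list, CORO1A of the leukocyte list (2.04-fold) and SCG2 and ENO2 of the neuroendocrine list (2.07-fold and 1.35-fold) fell. SCG2 was detected on 1 of 2 depleted arrays, and ENO2 did not pass with the replicate number as a block. Adjusted over the list alone, 3 prostate luminal, 1 urothelial, 1 fibroblast, 1 leukocyte, 1 endothelial and 2 neuroendocrine genes were lower and 2 urothelial genes higher. ESAM, the only endothelial marker detected, was below background on both depleted arrays and did not pass over all genes (adjusted p = 0.066). The leukocyte and neuroendocrine lists, the ones with enough detected genes for the set test, did not pass (list adjusted p = 0.98 and 0.48). No gene of the list of mitochondrially encoded transcripts was matched to a named probe.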

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

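DCAF1 stayed lower and past the threshold in every setting in which it was tested, with log2 fold changes from -1.61 to -1.20 when single arrays were left out. None of the 2559 calls became a call in the opposite direction in the 17 settings compared gene by gene, but counting all probes, 9 of the genes had another probe that passed the opposite way. Of the 96 other list members that are named and passed, 27 passed in every setting. The number of genes changed was 3872 at an adjusted p of 0.1 (1754 higher), 927 with treat (340 higher, 587 lower), and 830 to 1749 when single arrays were left out (294 to 742 higher, 533 to 1007 lower). In the fits without an array, the lone array of its group is assumed to vary like the other group. Scaling on the median of all probes gave 543 higher and 2376 lower, the deposited processed values 142 and 2504, and no scaling between arrays (chosen after seeing the data) 148 and 2475. These settings put the median of all genes at -0.16, -0.27 and -0.34. The deposited values also differ in their background, but no scaling alone, with the background correction kept, gave nearly the same counts. At least 2-fold changes numbered 172 without background correction (58 higher, 114 lower), 280 with an offset of 50 (101 higher, 179 lower) and 341 with the stricter detection filter (200 lower). With scaling on the median of all probes 92 were higher and 627 lower, in the deposited values 27 were higher, and with no scaling 1138 changed (59 higher, 1079 lower). Leaving out single arrays gave 510 to 632 (183 to 222 higher, 318 to 410 lower). No background correction leaves the background in every signal and the offset of 50 adds a larger constant, which makes folds smaller by construction. The stricter filter tests fewer genes (9676). The number of lists called was 0 with an estimated correlation, 4 with fry (3 of them among the 6), 1 with no scaling and 5 to 6 when single arrays were left out. With the replicate number as a block, 2995 genes changed (1315 higher, 1680 lower), 2518 of the 2559 calls stayed and 6 lists were called. Deviations of same-numbered arrays correlated at 0.14 over genes, and the labels do not say that a number marks a shared day, so the pairing is not established. Signal over background limits the sizes: 181 of the calls had a group below background.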

Other observations

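The tests of the 3 patterns weighed here were chosen after the results were seen, and the genes and classes described here were picked after their values were seen. Class II histocompatibility genes were lower in VprBP-depleted cells. Of 8 tested, 6 fell and 2 did not pass, with a median log2 fold change of -1.37 (-1.25 in the deposited processed values), and 4 fell without mock replicate 1. HLA-DRB1 fell 2.80-fold next to HLA-DPA1, HLA-DMA and HLA-DOB, while HLA-DRA (log2 fold change -0.20, limma adjusted p = 0.32) and HLA-DRB3 (-0.32, adjusted p = 0.12) did not pass. The invariant chain CD74, not counted among the 8, did not pass either (-0.053, adjusted p = 0.81). The near-identical HLA-DRB copies are uncertain, since their probes are not known to tell them apart. Of 6 class I genes (B2M included), 0 passed in limma after quantile normalization and 1 had an unadjusted p below 0.05, while 2 were lower in the deposited processed values.

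Several single genes are given beside those already named, with no test of a group. With IL11 and IL6R, IL6 rose 1.62-fold and SOCS3, a feedback inhibitor of this signalling, rose 2.59-fold, while LIF (log2 fold change 0.25, limma adjusted p = 0.34) and IL6ST (0.37, adjusted p = 0.086) did not pass. With CYP1A1, CYP1B1 rose 3.04-fold, whereas TIPARP, another target of the aryl hydrocarbon receptor, had a log2 fold change of 0.11 (adjusted p = 0.60). PCK2, a mitochondrial enzyme that makes phosphoenolpyruvate, fell 3.82-fold, and ARRDC4, a relative of TXNIP, rose 1.77-fold. In the deposited processed values IL6 (adjusted p = 0.20) and ARRDC4 (0.47) did not pass. Without VprBP-depleted replicate 1 or 2 neither passed (0.11 and 0.061 for IL6, 0.061 and 0.079 for ARRDC4), and IL6 did not without mock replicate 1 (0.069).

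Of 28 small nuclear and small Cajal body RNAs tested, 21 rose and none fell, against 8.8% of all genes that rose. Their median log2 fold change was 1.04 (95% bootstrap interval 0.84 to 1.33). The bootstrap drew RNAs of a class, not arrays, so the intervals given here hold no spread between arrays. Normalization between arrays is argued against as the whole cause, since without scaling the median was 0.69 (0.44 to 1.00), and 0.57 (0.37 to 0.70) in the deposited processed values, with 14 higher in each. Equal extra labelling of all RNA without a poly(A) tail is argued against by the small nucleolar RNAs. The H/ACA and C/D classes had medians of 0.25 (15 of 67 rose, 6 fell) and 0.22 (17 of 71 rose, 3 fell). Without scaling these were -0.061 and -0.10, where the median of all genes was -0.34. Both classes thus stood above all genes, but by less than the small nuclear and small Cajal body RNAs. A smaller extra labelling shared by these classes is not excluded. Of 12 other structural RNAs, 6 rose and 1 fell, with a median of 0.65 (-0.060 to 0.94). Replication-dependent histone mRNAs had a median of 0.11 (-0.081 to 0.36). They cannot decide alone, since a real fall with the DNA replication genes (9 of 51 fell) could mask extra labelling. Carry-over or priming of structured RNA that differs by class stays open, since the 18S and 28S ribosomal RNA probes rose as well (the lower log2 fold change was 0.89), although 1 of these 2 passed in the deposited processed values. An effect of VprBP on these RNAs was not tested and may also account for the rise.

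Higher genes made up 43.3% of the calls after quantile normalization and 5.64% with the same background correction and no scaling between arrays. Brightness that varies from array to array could account for the difference, since the mock arrays differed by 0.38 in median log2 brightness of detected probes and the groups by 0.36. Lower total mRNA in depleted cells cannot be told apart from it: the dimmer mock array exceeded the brighter depleted array by 0.029, and no spike-in values were used here.

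The fall of the unfolded protein response and ATF4 list was uneven. The 9 stress-signalling members had a median log2 fold change of -0.10 (PPP1R15A and CEBPB rose, and CHAC1 at -0.48, TRIB3 at -0.43 and SESN2 at -0.28 did not pass), against -0.47 for 13 amino acid genes (7 fell) and -0.47 for 14 chaperone and quality control genes (6 fell). Lower activity of the whole programme stays open: the medians of the stress-signalling members and the others (30 genes, median -0.55, among them DDIT4, CEBPG and VLDLR) differed by 0.44, but the members were divided after their values were seen, so this excludes nothing. Denser or more starved mock cultures cannot be told apart from an effect of VprBP. TXNIP rose by 1.55 on the log2 scale and 10 of 35 glycolysis and hypoxia genes fell (28.6%). Against this, 6 of 49 mitosis genes fell, but that share (12.2%) is close to the 11.6% of all genes that fell. Both camera calls were lost with an estimated correlation (adjusted p = 0.90 and adjusted p = 0.45). That version had 2 residual degrees of freedom and little power. For glycolysis and hypoxia the estimate was 0.11, above the preset 0.01, so low power need not be the only reason.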
